A study of Volvox carteri with 12 samples.

How the data were processed

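The libraries came from somatic cells and gonidia of Volvox carteri strain Eve10, grown at 28 °C in a light cycle of 16 h light and 8 h dark at about 100 µmol photons per square metre and second, per the labels' protocols. UV-B was given for 1 h at 0.056 mW/cm2, and polyA-selected RNA was sequenced on an Illumina platform, per the labels' protocols. The labels name 3 biological replicates per group, lettered A to C. Each deposited table holds the gene-level FPKM of a library with its 95% confidence limits and a status, per the file headers. TopHat2 version 2, Cufflinks 2.0.1 and Cuffdiff 2 are named in the submitters' processing notes. The genome build and the annotation are not given in the sources used here, and coordinates are given as in the deposited tables.

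Every deposited table listed its own gene rows, between 27527 and 33381 in the usable libraries, and only reference IDs recurred across them: 8623 distinct reference IDs were found, and 1334 of these were listed in every usable library. Rows were therefore matched by position. Rows of different libraries that overlapped by at least 80% of the longer row were linked, and a linked set with exactly 1 row from each of the 11 libraries was kept as a locus. This gave 9593 loci, of which 5679 carried a reference ID. Matching by overlap was chosen after the files had been seen, because the analysis had been planned on shared gene IDs. A locus that was assembled in some libraries only, divided differently between them, or expressed in too few cells to be assembled is missing from every comparison. Gene rows could overlap each other: 3600 matched loci were covered by more than 10% by another row of the same library, and fragments in the shared part are assigned by the authors' software.

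In the UV-B gonidia table of replicate A, all 4073 reference gene rows were at 0. The 3870 rows above 0 had confidence limits equal to their values, none exceeded 6.9006, and they summed to 3942.2, against 1763617 to 3849288 in the other libraries. This library was left out, so the planned fit on 12 samples was made on 11. Of the FPKM sum of a usable library, 55.6% to 80.1% lay in rows shorter than 200 bp. The matched loci held 14.9% to 38.1%. For this reason libraries were not compared by their FPKM sums. The tables used here give no fragment numbers. The confidence limits imply them under counting error (the squared ratio of a value to its standard deviation, taken from the upper limit), which gave 14640000 to 33960000 fragments per library and a median of 145 to 523 fragments per matched locus. Of the reference rows below 20 implied fragments, 86.2% to 90.8% came within 0.05 of a whole number. In loci with several isoforms the limits are wider than counting error, so these numbers were used to describe depth and in an added alternative only.

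Each library was divided by a median-of-ratios factor taken over loci above 1 FPKM in all 11 libraries. Loci with at least 1 FPKM in at least 3 libraries were kept, which left 7540. Values were analysed as log2(FPKM + 1), so fold changes of low loci are understated. A model with a mean for each of the 4 groups was fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and an intensity trend, and p-values were adjusted by the Benjamini-Hochberg method over all loci at a threshold of 0.05. The contrasts were UV-B against white light in each cell type, the difference of these responses, and somatic cells against gonidia in each light. Python 3.11.15 with pandas 2.3.3 was used for the matching. On simulated data with the estimated spread of each of the 7540 loci, the same procedure recovered 12.5% of 200 loci changed by 1 log2 unit and 85% of those changed by 2 log2 units in somatic cells. In gonidia, with the smaller UV-B group, it recovered 0.5% and 78.5%. The changed loci were drawn from those with a mean log2(FPKM + 1) above 2, so these rates do not cover lower loci.

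The replicate letters could pair the samples of a cell type. In somatic cells the deviations of same-letter libraries from their group means correlated at 0.351 for A, 0.447 for B and 0.202 for C, so the letters paired them within this cell type, from the data and not from a label that says what a letter shares. Gonidia had 2 such pairs, at 0.705 for B and 0.624 for C. With 2 UV-B gonidia libraries, the deviations of B and C from their mean mirror each other, so these values are not independent. Between the cell types in white light the same-letter correlations were 0.074, 0.144 and 0.0402. Under UV-B they were 0.172 for B and 0.0932 for C. All of these were positive but below those within either cell type, so whether a letter is shared by both cell types stays open.

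Design, tests, the rule for named loci and the settings listed next were fixed before the data were examined. None of the reference IDs was found in the table of 14334 RefSeq genes supplied with the data, which describes another gene set, and 0 start and end positions agreed. The planned gene lists, the camera test on them, the cell-type marker genes and the planned named genes (UV-B photoreceptor and its partners, photolyases, light-stress genes, regA) were therefore not analysed here. The rule for that case was at most 2 IDs up and 2 IDs down per contrast, by the largest log2 change among loci past the threshold whose groups do not overlap, filled by the smallest p; loci beyond it are given by position and were chosen after their values were seen. The settings varied by plan were a pseudocount of 0.1, no filter, a filter of 5 FPKM, FPKM as deposited, quantile normalization, the replicate letter as a block, only the groups compared, robust empirical Bayes, and each usable library left out. Added after the data had been seen were matching at 50% and 90% overlap, loci not overlapped by other rows under several limits, empirical library weights, a block for each cell type and letter, limma-voom on the implied fragments, and leaving out both B gonidia libraries, also from the counts of loci high in 1 cell type and low in the other.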

Results

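Volvox carteri is a multicellular green alga whose spheroids consist of small flagellated somatic cells, which do not divide, and large reproductive cells called gonidia, which give rise to the next generation. RNA was sequenced from somatic cells and gonidia of the wild-type strain Eve10, kept in white light or exposed to ultraviolet B light (UV-B) for 1 h at 0.056 mW/cm2, at a stage after maturation and before embryogenesis. The labels give 3 biological replicates, A, B and C, for each of the 4 combinations of cell type and light. The UV-B gonidia library of replicate A held no usable expression values, so 11 libraries were compared, with n = 2 for UV-B gonidia and n = 3 for the other groups. Values were fragments per kilobase of transcript, normalised to the mapped fragments (FPKM), and the confidence limits beside them implied between 14640000 and 33960000 fragments per library. After the gene rows of the libraries had been matched by position, 7540 loci were tested, of which 3685 carried a reference gene ID. The IDs were not paired with gene names, so loci are described by scaffold position and by the cell type in which they were higher.

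The libraries separated by cell type on the first principal component, which held 77% of the variance. It placed the somatic libraries between 60.1 and 69.5 and the gonidia libraries between -99.2 and -52.2. The gonidia libraries of replicate B, at -52.2 under UV-B and -52.9 in white light, lay nearer to the somatic libraries than the other gonidia libraries, which lay at -86.4 or below. At the 459 loci specific to somatic cells (at least 20 FPKM on average and at least 5 times the gonidial mean), the median level in these B libraries was 18.9% of the somatic mean under UV-B and 19.3% in white light. It was 3.18%, 3.35% and 5.83% in the other gonidia libraries. Across loci, the B gonidia libraries correlated with each other at r = 0.966 and with the other gonidia libraries at 0.905 to 0.926; loci are not independent replicates.

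**Figure D1:**
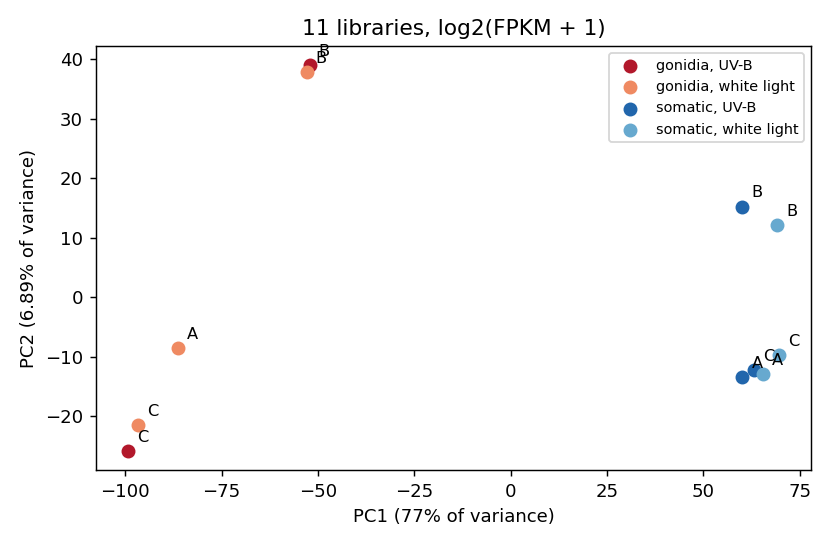
Principal components of log2(FPKM + 1) in the 11 libraries, with 1 point per library, coloured by cell type and light and marked with the replicate letter; the axes give component scores and their share of the variance (77% and 6.89%). Somatic libraries lie at 60.1 to 69.5 on the first component, and the B gonidia libraries lie at -52.9 and -52.2, apart from the other gonidia libraries.

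Somatic cells were compared first between UV-B and white light. Of the 7540 loci, 6 rose under UV-B and 0 fell (limma, adjusted p under 0.05), with 347 loci at an unadjusted p under 0.05, against 377 expected by chance. That fit ignores the replicate letters; with each cell type and letter as a block, chosen after seeing the data, 1388 loci had an unadjusted p under 0.05, 912 lower and 476 higher under UV-B, and 9 rose after adjustment, 3 of them among the 6 (limma). The 6 loci were listed at 0 or low in white-light somatic cells. Of these, 4 were lower there than in white-light gonidia (limma, adjusted p under 0.05), as were 34.7% of all loci tested. Both comparisons use the same white-light somatic libraries, so the 4 are no independent result. Under UV-B the somatic levels of the 6 loci came to 2.47 to 55.5 FPKM. The locus Vocar20002813m.g.2.0 (scaffold 2, 455263 to 456043) was listed at 0 in all 3 white-light somatic libraries and at 51.6, 55.5 and 49.6 FPKM in the UV-B somatic libraries (limma, adjusted p = 6.6e-07). In gonidia the same locus stood at 34.7 ± 4.23 FPKM (SD, n = 3) in white light and at 31.8 and 49.1 FPKM under UV-B. It lies inside a longer gene row (scaffold 2, from 452311), whose level was 138, 123 and 122 FPKM in the white-light somatic libraries and 97.6, 82.6 and 84.6 FPKM under UV-B. The locus at scaffold 34, 521074 to 525819, was also listed at 0 in all 3 white-light somatic libraries and rose to 12.3, 13.1 and 14.8 FPKM under UV-B (limma, adjusted p = 3.8e-05). Its levels in gonidia were between 8.53 and 15.3 FPKM in both lights, and neighbouring gene rows adjoin or overlap it at both ends.

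The other 4 loci, given by position and chosen after their values were seen, were low but measured in white-light somatic cells. The locus at scaffold 1, 776071 to 778158, rose from 0.67 ± 0.481 to 15.6 ± 6.78 FPKM (SD, n = 3 each), a log2 change of 3.24 ± 0.39 (SE). The locus at scaffold 6, 2513784 to 2522154, rose from 0.687 ± 0.254 to 9.04 ± 3.72 FPKM (SD, n = 3 each), a log2 change of 2.50 ± 0.31 (SE). No other row overlapped it, but its row began further left, at 2513073 and 2512926, in the UV-B somatic libraries A and C (11 and 11.3 FPKM) than in the UV-B somatic library B (4.75 FPKM) and the white-light somatic libraries, where it began at 2513784 or, in white-light library A, at 2513635. The loci at scaffold 1, 2447004 to 2453992, and at scaffold 1, 12663118 to 12670426, rose from 0.243 ± 0.081 to 4.32 ± 1.55 FPKM and from 0.429 ± 0.231 to 2.64 ± 0.232 FPKM (SD, n = 3 each). In the deposited tables the rows of 776071, 2447004 and 12663118 were longer in each UV-B somatic library than in each white-light somatic library. The first ended at 778234 to 778428 against 778158, the next began at 2445393, 2446516 and 2446472 against 2447004, and the last ended at 12670503 to 12670587 against 12670426. Longer rows cover the locus at 12663118 in full in every library but the white-light gonidia library B, and another row overlaps 2447004 in the UV-B somatic library A. All 4 had adjusted p = 0.023 in limma. With the replicate letter as a block shared by both cell types, adjusted p was 0.0098 at 776071 and 0.0062 on scaffold 6, while both other loci missed the threshold at 0.057 (limma). With each cell type and letter as a block, only scaffold 6 of these 4 kept its call, at adjusted p = 0.046, and 776071 missed it at 0.088 (limma). Quantile normalization ended all 4 calls and left 2 loci. The count also fell to 2 without the white-light somatic library A or the white-light gonidia library A and to 3 (2 of them the same loci) without both B gonidia libraries, was 4 (2 of them the same loci) without the UV-B somatic library C, 6 (3 the same) without the UV-B somatic library A and 8 (3 the same) without the white-light somatic library B. It rose to 12 (2 the same) without the white-light somatic library C and to 27 (6 the same) without the UV-B somatic library B.

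In limma on FPKM with all 11 libraries weighted equally, no locus passed the threshold for a fall in somatic cells. With all 11 libraries and empirical library weights 40 loci rose and 5 fell, and with limma-voom on the implied fragments 4 rose and 1 fell. Falls also passed when a library was left out: 6 without the UV-B somatic library B, and 2 each without the UV-B somatic library A, the UV-B somatic library C or the white-light somatic library C (limma). The lowest p belonged to scaffold 9, 1879487 to 1885461, at 20.3 ± 2.43 FPKM in white light and 9.47 ± 1.07 FPKM under UV-B (SD, n = 3 each; limma, adjusted p = 0.075, and 0.0113 with library weights). Another row overlapped this locus from 1882032, 1882032 and 1881987 in the UV-B somatic libraries A, B and C (10, 1.07 and 2.06 FPKM) and from 1881978 in the white-light somatic library A (4.05 FPKM), while in the white-light somatic libraries B and C it began at 1885420 and was listed at 0. The libraries of the 2 lights did not overlap at 640 loci that were lower and 344 loci that were higher under UV-B. Chance gives 5% of the loci, 377, in each direction if the somatic libraries are exchangeable. The letter pairs break that condition, so neither count was tested against a valid chance level.

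**Figure D2:**
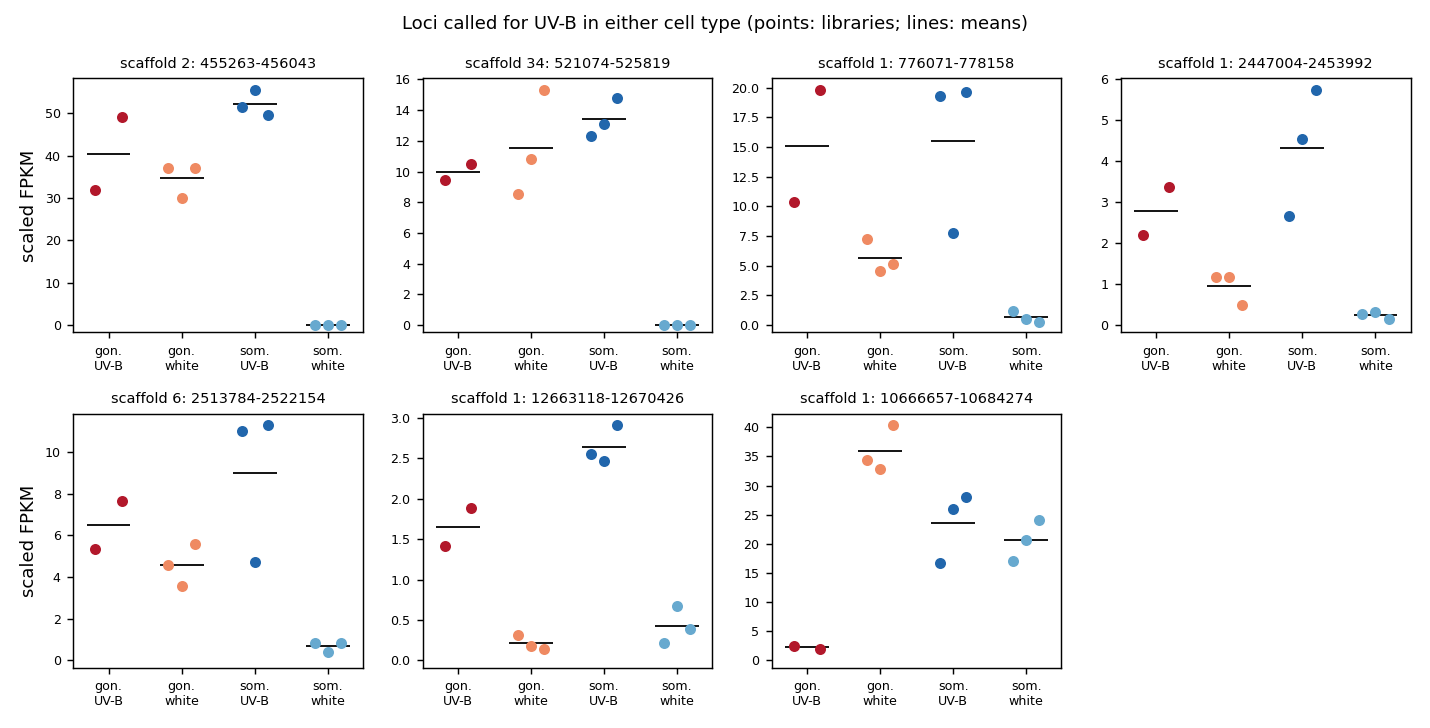
Scaled FPKM (vertical axis, linear, a separate scale in each panel) of the 7 loci that passed the threshold for UV-B in either cell type, with 1 point per library and a line at each group mean (n = 2 for UV-B gonidia, n = 3 otherwise). The panels on scaffold 2 and scaffold 34 show 0 in all white-light somatic libraries. The last panel shows the locus called in gonidia, at 2.48 and 2.03 FPKM under UV-B, where its row was divided.

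In gonidia, 1 of the 7540 loci fell under UV-B and 0 rose (limma, adjusted p under 0.05), with 135 loci at an unadjusted p under 0.05. With each cell type and letter as a block 374 loci had an unadjusted p under 0.05, against 377 expected by chance, and 2 fell after adjustment, the reported locus among them (limma). This locus lies at scaffold 1, 10666657 to 10684274, and stood at 35.9 ± 3.98 FPKM in white light (SD, n = 3) against 2.48 and 2.03 FPKM under UV-B, a log2 change of -3.50 ± 0.25 (SE; limma, adjusted p = 0.00089). In both UV-B gonidia libraries this stretch was divided in the deposited tables. Its left part, 10666681 to 10668690, formed a separate row at 33.4 and 43.0 FPKM there, and the low value belongs to the remainder. In white light the undivided row held 34.4, 32.8 and 40.4 FPKM, so the call compares unlike stretches and shows no fall of the whole. With limma-voom on the implied fragments the log2 change was -1.52 and the call was lost (adjusted p = 0.508), as was the difference from somatic cells (adjusted p = 0.635). With only the gonidia libraries in the limma fit adjusted p was 0.076. Among loci that did not pass with the reported settings, scaffold 4, 3776509 to 3785264, was at 1.52 and 1.51 FPKM under UV-B and at 0.153, 0 and 0 FPKM in white light (limma, adjusted p = 0.24); it passed with a pseudocount of 0.1 (adjusted p = 0.0479). The locus at scaffold 1, 12663118 to 12670426, which rose in somatic cells, was at 1.42 and 1.89 FPKM in UV-B gonidia and at 0.315, 0.18 and 0.139 FPKM in white light (limma, adjusted p = 0.32 in gonidia). The locus with the next lowest p for a fall, scaffold 13, 2032350 to 2055218, was at 0.074 and 0.017 FPKM under UV-B and 1.06, 1.77 and 2.31 FPKM in white light (limma, adjusted p = 0.22); it passed without a filter on low values (adjusted p = 0.033). In that fit of the gonidia libraries 0 loci passed in limma, with 82 at an unadjusted p under 0.05. Without both B gonidia libraries 14 loci rose and 12 fell, without the white-light library B 7 rose and 2 fell, without the UV-B library B 5 rose and 6 fell, and without the UV-B library C 5 rose and 13 fell; a lone UV-B library is assumed to vary like the other groups. Only falls passed without the white-light library A (3), the white-light library C (2) or the white-light somatic library A (2).

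The UV-B response was then compared between the cell types. At 3 loci it was more positive in somatic cells than in gonidia, and at 0 loci less positive (limma, adjusted p under 0.05), with 161 loci at an unadjusted p under 0.05, against 377 expected by chance. With each cell type and letter as a block, 547 loci had an unadjusted p under 0.05, 230 more and 317 less positive in somatic cells, and the same 3 loci passed adjustment (limma). The 3 loci were Vocar20002813m.g.2.0, the locus at scaffold 34, 521074 to 525819, and the locus at scaffold 1, 10666657 to 10684274 (limma, adjusted p = 4.0e-05, 0.0010 and 0.0027). At the last of these the row was divided in UV-B gonidia, so its difference compares unlike stretches. For the other 4 loci that rose in somatic cells no difference from gonidia passed the threshold, and their log2 changes in gonidia, between 0.42 and 1.24, had the same sign. Without both B gonidia libraries the response was more positive in somatic cells at 8 loci and less positive at 6. These counts were 8 and 4 without the UV-B gonidia library B, 12 and 3 without the UV-B gonidia library C, 7 and 1 without the white-light somatic library C, 3 and 2 without the UV-B somatic library B or C, and 5 and 0 without the white-light gonidia library A. Of the loci called in somatic cells, 0 were also called in gonidia. Across the 7540 loci, the UV-B log2 changes of the 2 cell types correlated weakly, at Pearson r = 0.0909 and Spearman rho = 0.106. These share no library. Without the UV-B gonidia library C the correlation was -0.037, and without the UV-B gonidia library B it was 0.157.

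Somatic cells and gonidia differed at most loci in white light. Of the 7540 loci, 2614 were higher in gonidia and 2042 were higher in somatic cells (limma, adjusted p under 0.05), and 78.7% of these differed at least 2-fold. The balance of directions moved with the scaling: 2738 and 1471 loci passed on FPKM as deposited and 2323 and 2252 after quantile normalization. With limma-voom on the implied fragments, which changes the values, their weights and the scaling together, 2139 and 2380 passed, a somatic majority. A difference of at least 8-fold was found at 309 loci higher in gonidia and 367 loci higher in somatic cells. Of the loci tested, 20 had at least 10 FPKM in every gonidia library and less than 0.5 FPKM in every somatic library, and 3 had the reverse. With the B gonidia libraries, which stood at 18.9% and 19.3% of the somatic level at somatic-specific loci, not considered, the counts were 27 and 21. The 20 loci include Vocar20007903m.g.2.0 (scaffold 15, 1869453 to 1871963), at 82.3 ± 7.88 FPKM in white-light gonidia (SD, n = 3) and listed at 0 in all somatic libraries (limma, adjusted p = 5.3e-08). A neighbouring row that overlaps its left end in most libraries went the other way, from 52.6 to 171 FPKM in the somatic libraries and from 0.876 to 10.8 FPKM in gonidia, and a value of 0 beside such a row is not a measure of absence.

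Some of the largest log2 changes came from differently divided rows. The locus with the largest value for gonidia, Vocar20013142m.g.2.0 (scaffold 30, 1210655 to 1219604), had 0.724, 1080 and 1890 FPKM in the white-light gonidia libraries and less than 0.04 FPKM in each white-light somatic library (limma, adjusted p = 0.014). In the 2 libraries with the high values its row began at 1208820 and took in a neighbouring abundant row. The locus with the largest value for somatic cells, Vocar20005452m.g.2.0 (scaffold 11, 1600149 to 1600910), was at 71.2 ± 22.2 FPKM in white-light somatic cells (SD, n = 3) and listed at 0 in the 3 white-light gonidia libraries, but at 32.2 FPKM in the UV-B gonidia library B (limma, adjusted p = 0.00051). Other gene rows overlap this locus. Next came scaffold 34, 802417 to 838485, at 113 ± 18.9 FPKM in somatic cells and 4.39 ± 6.49 FPKM in gonidia in white light (SD, n = 3 each; limma, adjusted p = 0.00030).

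Under UV-B the cell types differed in the same way. In this light 2308 loci were higher in gonidia and 1746 were higher in somatic cells (limma, adjusted p under 0.05). Here too the balance of directions moved, to 2111 and 1268 on FPKM as deposited, 2009 and 2020 after quantile normalization, and 1884 and 1993 with limma-voom. Of the loci called with the reported scaling, 2176 and 1642 were also called in the same direction in white light, where independent lists would share 800 and 473, and 2 loci were called in opposite directions. The cell-type log2 changes in the 2 lights, which share no library, correlated across loci at Pearson r = 0.951 and Spearman rho = 0.946. Without both B gonidia libraries, which held more RNA of somatic-specific loci, 2150 loci were higher in gonidia and 1875 in somatic cells under UV-B, and 2538 and 2139 in white light. The median of all loci was -0.21 (log2, somatic minus gonidia, white light) after scaling, -0.39 on FPKM as deposited and -0.046 after quantile normalization, so changes are relative to the scaling. Without the UV-B gonidia library C, 1838 loci were higher in gonidia and 915 in somatic cells under UV-B.

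**Figure D3:**
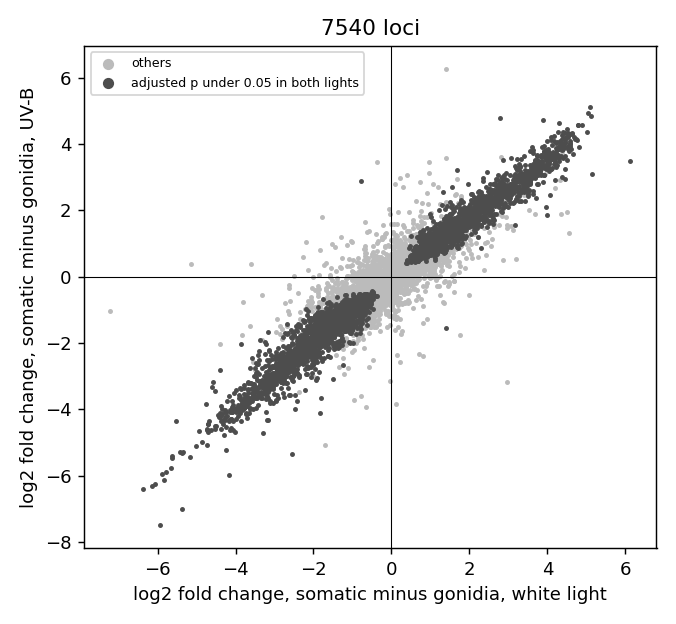
Log2 fold change of somatic cells over gonidia in white light (horizontal axis) and under UV-B (vertical axis) for the 7540 loci, with 1 point per locus; dark points passed an adjusted p of 0.05 in both lights. Most dark points lie along the diagonal, 1642 of them higher in somatic cells and 2176 higher in gonidia in both lights.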

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

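The test of overlapping gene rows was chosen after the result was seen. The count over other splits of the libraries was stated before its result was seen, but after principal components and correlations had been examined. At 3 loci the UV-B response differed between somatic cells and gonidia by the interaction term of limma. The difference of the UV-B log2 changes, somatic cells minus gonidia, was 5.54 at Vocar20002813m.g.2.0, 4.01 at scaffold 34, 521074 to 525819, and 3.67 at scaffold 1, 10666657 to 10684274. Where a group is listed at 0 this difference depends on the pseudocount and is no measure of size. At scaffold 1, 10666657 to 10684274, it rests on a row that was divided in UV-B gonidia. The UV-B gonidia library of replicate A, which entered no comparison, held 3870 rows above 0, and none of them was a reference gene row. Single outlying values were not tested within the groups, which hold 2 or 3 libraries each.

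The 6 loci called for UV-B in somatic cells may owe their calls to UV-B or to the assignment of fragments between overlapping or differently divided gene rows. The locus called in gonidia was a divided row. Of all 7 called loci, 4 were overlapped by more than 10% by another row, against 40.4% of all loci tested (two-sided Fisher's exact test, p = 0.451). This decides nothing for so few loci, and it counts overlap only, so rows divided or extended differently escape it. At the locus called in gonidia, the undivided row held 34.4, 32.8 and 40.4 FPKM in white light. Under UV-B its left part alone held 33.4 and 43.0 FPKM, which argues against a fall of the whole stretch. The remainder formed no separate row in white light, so its own change was not measured. Single loci show why the question stays open in somatic cells: Vocar20002813m.g.2.0 went from 0 to about 50 FPKM while the row around it went from 122 or more to 97.6 FPKM or less. The locus at scaffold 6, 2513784 to 2522154, was overlapped by no other row. Its row began at 2513073 and 2512926 in the UV-B somatic libraries with 11 and 11.3 FPKM and at 2513635 or 2513784 in the other somatic libraries. The UV-B somatic library B had the same row as the white-light somatic libraries B and C, at 4.75 FPKM against 0.394 and 0.821. No other row lay within 300 bp of this locus in any somatic library, so no overlapping row was seen to exchange fragments with it. The comparison on the same row rests on 1 UV-B library, so an effect of the differently extended rows stays open. The assignment of fragments stays open as well at the other 3 loci measured in white light, whose rows were longer in every UV-B somatic library. At 776071, though, the adjoining row on its left did not overlap the locus in any somatic library. That row rose too, from 9.88, 5.78 and 10.4 FPKM in white light to 16.2, 25.2 and 20.6 FPKM under UV-B. No loss of fragments from it was therefore seen. The call on scaffold 6 was lost in 9 of its 30 alternatives, with adjusted p between 0.00106 and 0.375 (limma). Those at 776071, 2447004 and 12663118 on scaffold 1 were lost in 12 of 28, 10 of 23 and 14 of 27 (limma). Over the 10 splits of the 6 somatic libraries, 2 gave as many calls, with 6 in the real split and 6 as the highest of the others, and 10 splits are too few for a share under 0.05; the other splits that part all 3 letter pairs gave 1, 2 and 3 calls.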

How the results depend on the processing

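Alternatives on gene matching, overlap, library weights, a block for each cell type and letter, limma-voom and both B gonidia libraries were chosen after seeing the data. The cell-type counts kept within 1.5 times of 4656 in white light and 4054 under UV-B in every setting chosen beforehand that used all usable libraries. With each library left out in turn they ranged from 4079 to 4745 and from 2753 to 4082. The UV-B counts are small and moved: from 1 to 18 in gonidia, from 2 to 27 in somatic cells and from 3 to 15 for the difference between cell types with each library left out, and the correlation of the UV-B changes ranged from -0.037 to 0.157. The replicate block gave 1, 6, 3, 5066 and 4450 loci (gonidia, somatic cells, their difference, cell types in white light and under UV-B); in somatic cells 4 of its 6 calls were among the 6 reported, and in gonidia and for the difference it kept the reported loci. For gonidia, the count was 2 with a pseudocount of 0.1, 4 without a filter and 0 with only the 2 groups compared. It was 2 at 50% and 0 at 90% reciprocal overlap, and 2 with a block for each cell type and letter. With limma-voom on implied fragments it was 0 over all loci and over loci not overlapped by rows of up to 50 kb. For somatic cells it was 2 after quantile normalization, 3 with only the 2 groups compared, 45 with empirical library weights (40 higher, 5 lower), and 2 with limma-voom on loci not overlapped by rows of up to 50 kb, where the difference between cell types gave 0. Restricting the test to loci not overlapped by more than 10% left 4492 loci. This gave 2 loci in somatic cells, 1 for the difference (the row divided in UV-B gonidia), and 2843 and 2522 between cell types. Without any overlap these counts were 1, 0, 1368 and 1198, and 0 in gonidia, with 2103 loci tested. With overlap by rows of up to 50 kb alone considered, loci under the 10% limit gave 3 for somatic cells and 1, the same divided row, for the difference. Loci without overlap gave 0 in gonidia, 2, 0, 1586 and 1402. Fewer loci were tested in each of these. Without both B gonidia libraries the counts were 26, 3 and 14. The correlation of the UV-B changes was 0.0145 with library weights, 0.174 without any overlap and 0.173 without overlap by rows of up to 50 kb. Where not shown by the number of loci or libraries, the cause was not tested. Both loci listed at 0 in white-light somatic cells stayed called in all of their 25 alternatives. Other rows overlap them by up to 100% (scaffold 2) and 11.9% (scaffold 34). The settings limited to loci not overlapped by other rows therefore left both out and could not test them. Camera alternatives were not run, since no gene list was matched, and leaving out the UV-B gonidia library A did not apply. In simulated libraries, drawn independently with the spread of the reported fit and without letter pairs, changes of 1 log2 unit were mostly missed. Of these, 12.5% were recovered in simulated somatic libraries and 0.5% in simulated gonidia libraries. Recovery in a fit that uses the letters was not simulated. Loci with a mean log2(FPKM + 1) of 2 or less were not among those changed.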

Other observations

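Tests of the loci specific to a cell type, apart from that of gonidial RNA in the UV-B somatic libraries, of neighbouring loci and of the other splits were stated before their results were seen, after principal components and correlations over all loci had been examined; that test and the test of the B share alone were stated afterwards. The loci specific to somatic cells stood lower under UV-B in each pair of somatic libraries. Over these 459 loci the median UV-B log2 change was -0.32 in pair A, -0.36 in pair B and -0.34 in pair C, while over the 385 loci specific to gonidia it was -0.07, -0.04 and -0.10, and over all loci -0.04, -0.03 and -0.03. The direction held on FPKM as deposited, with a median of -0.21 against 0.05 for all loci, and after quantile normalization, with -0.19 against -0.01. The sets were chosen on means over both lights, so their choice does not favour a direction. They were not matched for level. In the somatic libraries the gonidia-specific loci stood at a median of 6.92% to 10.5% of the gonidial level, and log2 changes of low loci are understated. Whether other loci as abundant in somatic cells also stood lower under UV-B was not tested. In the reported fit no locus of this set passed the threshold for a fall; 1 passed with empirical library weights and 1 without the UV-B somatic library B (limma). Of the gonidia-specific loci, 2 passed for a fall without the UV-B somatic library B and 1 without the UV-B somatic library A, so the few calls do not set the sets apart. The 3 pairs are too few for an exact sign test of the medians to reach a p under 0.05.

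With each cell type and letter as a block, 1388 loci had an unadjusted p under 0.05 for UV-B in somatic cells, 912 lower and 476 higher, and 9 passed adjustment (limma). With the lights exchanged in pair B, in pair C or in both, the same fit gave 285, 293 and 226 loci. There are 4 such arrangements, too few for a share under 0.05.

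The UV-B somatic libraries lay nearer to the gonidia libraries on the first principal component, at 60.1, 60.1 and 63.1, than the white-light somatic libraries, at 65.4, 69.1 and 69.5. Gonidial RNA carried over into the UV-B somatic libraries would raise the gonidia-specific loci there, but between libraries of the same letter the median share of the gonidial level differed by -0.72 (A), 0.01 (B) and -0.61 (C) percentage points, UV-B minus white light. The median difference over these 385 loci had a 95% bootstrap interval whose upper end was 0 or below in each pair, which argues against it; it covers the spread over loci only. The lower level of somatic-specific loci, with a highest median of -0.32 over the 3 pairs, describes the same shift, since this component separates the cell types, and is no separate support for it. A response of somatic cells to UV-B is a candidate explanation, and a difference in handling between the lights stays open, since the design does not separate it.

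The B gonidia libraries lay nearer to the somatic libraries in both lights. At somatic-specific loci their share was at least 3.24 times that of any other gonidia library, which is consistent with somatic RNA in these libraries. That RNA alone does not account for the shift: gonidia-specific loci were lower than the share implies by at least 0.21 on the log2 scale in all 6 comparisons with another gonidia library (an excess of -0.207). Over 584 loci at about equal level in the cell types, the difference of the UV-B library B from C correlated with that of the white-light library B from A at r = 0.431. A difference of replicate B beyond such RNA, for example in stage, may therefore contribute. The labels do not say what a letter shares, so its source was not tested.

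Neighbouring loci tended to differ between the cell types in the same direction. Among 1336 pairs of called loci lying 1000 to 10000 bp apart, 56.7% shared their direction, against a median of 50.7% in 100000 shuffles (one-sided permutation p = 2e-05). Among the 428 pairs in which both loci carried their own reference ID it was 63.8% against 54.9% (one-sided permutation p = 2e-04). Shared regulation of neighbours is a hypothesis here; transcripts that run on into the next locus, or genes divided into several rows, could give the same share of 56.7%.

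For the cell types in white light, 1 of the 10 splits of the 6 libraries gave as many loci, the real split with 4656, and the highest of the others gave 1. With 10 splits a share under 0.05 cannot be reached.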
